A study of Oncorhynchus mykiss with 42 samples.

How the data were processed

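Messenger RNA was measured in rainbow trout testis on 42 nylon membranes, each carrying 9216 spotted positions in 64 blocks of 144. Per the labels, 5 µg of total RNA per sample was copied into cDNA carrying radioactive phosphorus (33P). Each sample was hybridised alone, so an array holds 1 channel. The authors deposited, per the file headers, 1 export of the AGScan image program per array, with several columns of spot intensity and no local background column. The column of image signal over a constant spot diameter was used on its linear intensity scale. A table of log2 values for the whole series was also deposited by the authors, and its normalization is not given in the sources used here. Its column medians lay between 7.15 and 7.17. Set against the scanner values it ran in the same direction, on a log2 scale and with clones not centred. It differed from quantile-normalised log2 signal by an SD over clones of 0.17 (median over arrays). Clones were assigned to positions by minimising that difference, so the SD is small partly by construction. Across arrays, the correlation of the table with the image signal had a median of 0.83 over clones. What produced the remaining difference stays unknown.

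The scanner exports name grid positions, and the deposited log2 table names clones, so clones were assigned to positions by their profiles over the 42 arrays. Of 9216 table rows, 8175 held values and 1041 were empty on every array. The empty rows comprised 64 named water, 128 sharing the ID cvu03687 and 849 clones. Each row with values was paired with 1 position by minimising the summed squared difference, and 93.3% of the pairs were also the nearest position. In simulated rows with independent noise at the median spread of the matches, 99.99% returned to their true position. Real rows varied in spread, so that share may overstate how well the clone IDs were assigned. Positions A07, A11 and A12 of every block, 192 in all, received 1 clone between them, and their number equals that of the water and cvu03687 rows. They were taken as control positions on that inference and left out before normalization, which left 9024 clone positions. The files do not pair clones or positions with genes, and the gene table of assembly USDA_OmykA_1.1 holds no clone IDs, so 0 of the 21 gene lists fixed beforehand, the cell type marker lists among them, could be tested.

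Log2 signals of the 9024 positions were quantile normalised between the 42 arrays. No background correction was applied, as no background column exists. A linear model with the 8 group means was fitted to each position in limma 3.58.1 (R 4.3.3), followed by empirical Bayes moderation. The two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was called. All adjusted p-values given are from this limma fit. On simulated data with 200 changed positions for FSH in stage I-II, the fit recovered 64% of changes of 0.5 on the log2 scale and 100% of changes of 1, with 10 false calls among 9024 positions. For the stage comparison at T0 it recovered 16% and 92% of those sizes, with 4 false calls. The simulated noise was independent between positions. It leaves out shared shifts of neighbouring spots, so these rates may not hold on the membranes.

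A position was taken as above background where its signal exceeded the median of the A07 positions plus 3 scaled median absolute deviations on that array. This was computed on linear signals, after a first version on log2 values had been tried, and both are given in the closing section. Thresholds ran from 52.0 to 140 intensity units, and 58.0% to 76.7% of clone positions exceeded them per array. Where no array of a group exceeded its threshold, a fold is given as a lower bound, from the bright group's mean against the dim group's mean of the higher of its own value and the lowest value above background on each array. The number of arrays per group limits the precision.

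The rule fixed for naming genes needs gene symbols. In its place, chosen once the absence of names was known, each comparison names the 2 clones with the greatest rise and the 2 with the greatest fall among those called, or fewer where fewer were called. A touching position is one of the 8 around a spot in its block, control positions apart. The other settings fixed beforehand were median centring, cyclic loess, the deposited log2 table, filters on dim spots, trended and robust moderation, array weights, fits on the compared groups alone, the column order of the scanner export as a block and leaving out each array. Others were added after the data were seen: the fitted signal column, equal block medians, matched spots alone, the control level as covariate, control spots in the normalization, leaving out spots beside far brighter ones, counting touching calls once, and leaving out the 3 arrays with another export order. The comparisons, groups, main test and first list of other settings were fixed before the data were examined. The replicate numbers of the labels differ between all groups, so nothing was paired. The labels give replicates as separate incubations of fragments and do not tie them to fish, so p-values measure the spread between these samples. Matching and figures used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.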

Results

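Testis fragments of all-male rainbow trout were profiled before culture (T0) and after 96 h at 12 °C without hormone (Ctrl) or with 500 ng/mL of purified salmonid FSH or LH, the pituitary gonadotropins that act on the testis. Medium was changed at 48 h. Testes at stages I-II and III of development were used. Each stage had 3 T0 arrays and 6 arrays each of Ctrl, FSH and LH, 42 in all. The median clone signal per array ran from 85 to 171 intensity units, and the scanner's highest reading was 34468. Several arrays shared exactly this maximum, so their brightest spots may have reached a ceiling. Clones are given by ID, since the files do not pair them with genes. Values are log2 signals after quantile normalization, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 9024 clone spots.

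The first 2 principal components held 31.7% and 13.4% of the variance. T0 arrays lay at 27.2 to 48.5 on the first component and cultured arrays at or below 5.46. FSH and LH arrays of a stage overlapped on both components.

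**Figure D1:**
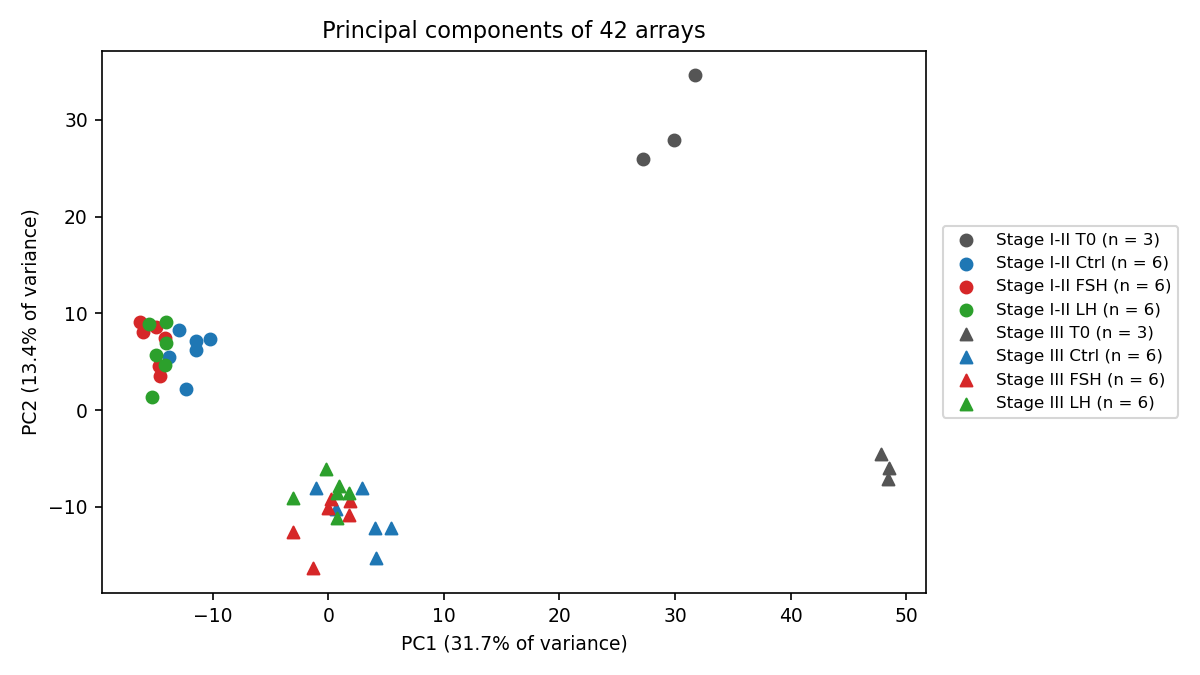
Each point is 1 array on the first (x) and second (y) principal component of log2 signal, coloured by treatment, with circles for stage I-II and triangles for stage III. T0 arrays lie to the right, at 27.2 or more, and cultured arrays at 5.46 or less.

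The first question was which transcripts responded to FSH in stage I-II. Clone 1rt34l03_b_f02 rose from 6.73 ± 0.17 in Ctrl to 10.45 ± 0.20 with FSH (SD, n = 6 each), a 13.2-fold rise (log2 change 3.72 ± 0.12 SE, limma adjusted p = 2.2e-27). Clone tcbk0013.j.13 rose 9.34-fold, from 7.45 ± 0.48 to 10.68 ± 0.24 (SD, n = 6; limma adjusted p = 1.7e-20). Clone tcac0002.e.17 fell by 1.55 on the log2 scale, from 8.73 ± 0.19 to 7.18 ± 0.12 (SD, n = 6; limma adjusted p = 3.2e-13), and touched a spot over 4 times brighter. Clone tcad0001.l.19 was not well above background on any FSH array and was at least 1.20-fold lower there (limma adjusted p = 4.4e-07). The ID of 1rt34l03_b_f02 rests on a profile match with a root mean square difference of 0.36 on the log2 scale, against a median of 0.19 over clones, and the same holds for tcbk0062.j.01 and 1rt113p07_b_h04, named further on. Each named clone lay beyond the control mean on 6 of 6 FSH arrays. In all, 148 spots rose and 85 fell, of which 18 and 3 changed at least 2-fold. Of these 233 spots, 102 touched a spot over 4 times brighter, and 140 spots were called when all such spots were left out of the test. The count was 140 in the deposited log2 table, 135 with the fitted signal and 350 with equal block medians.

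In stage III the same 2 clones led the FSH response. Clone 1rt34l03_b_f02 rose 8.16-fold, from 6.26 ± 0.16 to 9.28 ± 0.32 (SD, n = 6; limma adjusted p = 1.2e-23), and tcbk0013.j.13 rose 6.36-fold, from 6.44 ± 0.29 to 9.11 ± 0.16 (SD, n = 6; limma adjusted p = 2.8e-17). Each was above background on 3 of the 6 Ctrl arrays. Clone tcbk0039.n.08 fell by 0.99 on the log2 scale (± 0.12 SE, limma adjusted p = 1.5e-07) and tcag0001.c.01 fell by 0.94 (± 0.13 SE, limma adjusted p = 1.2e-06), each on 6 of 6 arrays. In all, 90 spots rose and 76 fell, and 298 spots were called with equal block medians. Of the calls at both stages, 53 spots rose and 49 fell in both, and none changed in opposite directions. Independent lists would share 1.48 and 0.72. Those expected numbers leave out that neighbouring spots move together and have the same neighbours in every comparison. Overlaps were not recounted without spots beside far brighter ones.

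LH in stage I-II raised the same leading clones, 1rt34l03_b_f02 by 10.5-fold (to 10.12 ± 0.23, SD, n = 6; limma adjusted p = 1.1e-25) and tcbk0013.j.13 by 8.68-fold (to 10.57 ± 0.25, SD, n = 6; limma adjusted p = 6.4e-20). Clone tcac0002.e.17 fell by 1.26 on the log2 scale (limma adjusted p = 5.0e-10). Clone tcay0031.p.13 fell by 1.00 (± 0.27 SE, limma adjusted p = 0.044), and its call was lost under 4 other settings, with a limma adjusted p of 0.061 to 0.103. It was also lost in 7 of 12 fits with 1 array left out. Over the 12 fits the change ran from -1.17 to -0.70, the latter without LH replicate 32 (limma adjusted p = 0.211). In all, 111 spots rose and 47 fell. The count was 50 with the control spots' level as covariate, 76 with the fitted signal, 357 with equal block medians and 373 with array weights. The deposited log2 table gave 136 higher and 107 lower.

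LH in stage III raised tcbk0013.j.13 by 7.55-fold (to 9.36 ± 0.24, SD, n = 6; limma adjusted p = 8.8e-19) and 1rt34l03_b_f02 by 6.78-fold (to 9.02 ± 0.17, SD, n = 6; limma adjusted p = 5.4e-22), each above background on 3 of the 6 Ctrl arrays. Clones 1rt116k18_c_f09 and tcac0002.e.17 fell by 0.85 (limma adjusted p = 1.6e-05) and 0.83 (limma adjusted p = 1.6e-05) on the log2 scale, each on 6 of 6 arrays. In all, 52 spots rose and 22 fell. The count was 46 in the deposited log2 table, 38 in a fit on the compared groups alone and 120 with equal block medians. LH calls at both stages comprised 35 spots that rose and 10 that fell in both, where independent lists would share 0.64 and 0.11. These expected numbers also leave out that neighbouring spots move together.

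**Figure D2:**
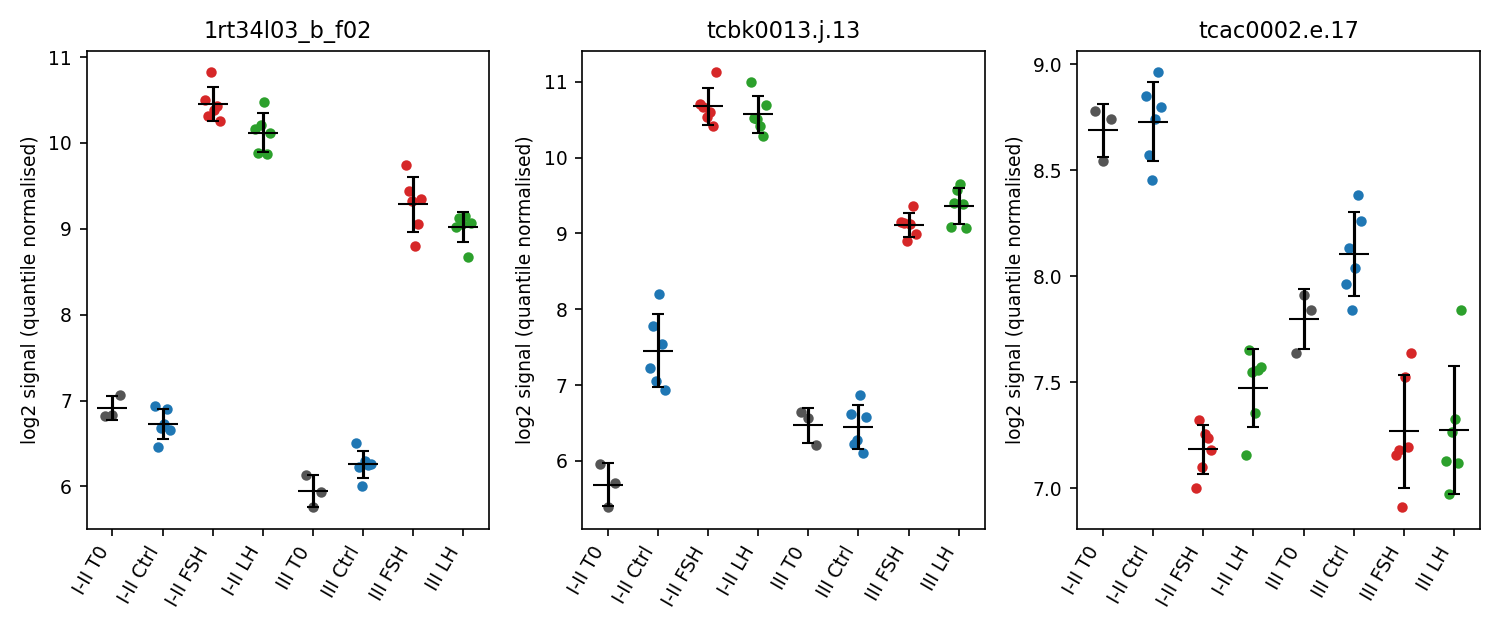
Log2 signal (y) of the 2 clones with the greatest rises and of tcac0002.e.17 in the 8 groups (x); each point is 1 array, and lines and bars are the group mean and SD. FSH and LH arrays of 1rt34l03_b_f02 have means of 9.02 to 10.45, against 6.26 and 6.73 in the cultured controls.

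**Figure D3:**
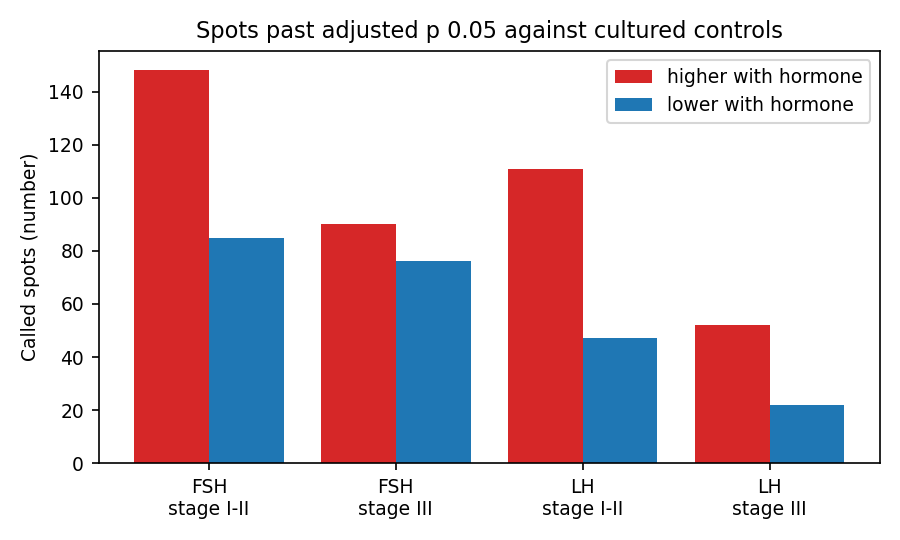
Number of spots called (y) for each hormone and stage against the cultured controls of that stage (x), split by direction; n = 6 arrays per group. FSH in stage I-II gave 148 higher and 85 lower, LH in stage III 52 and 22.

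FSH and LH responses overlapped within each stage. In stage I-II 69 spots rose and 31 fell with both hormones, against 1.82 and 0.44 for independent lists. In stage III 38 rose and 14 fell, against 0.52 and 0.19. The numbers for independent lists again leave out that neighbouring spots move together. The deposited log2 table gave 76 and 31 shared clones in stages I-II and III, and an adjusted p under 0.01 gave 62 and 31. Both hormones were compared with the same Ctrl arrays. Unchanged groups simulated against shared controls gave an overlap of 0, but groups without change yield almost no calls by construction, so this value does not show how much the shared controls add. The correlation of log2 changes across spots, which are not independent replicates, was 0.65 in stage I-II and 0.56 in stage III, where the simulation gave 0.50 for each. The covariance was 0.025 and 0.017, against 0.0093 simulated for each. With 3 controls for each hormone, the median correlation over 20 splits was 0.39 in stage I-II and 0.14 in stage III, with covariances of 0.018 and 0.0057. In the same splits a median of 38 spots rose and 11 fell with both hormones in stage I-II, and 21.5 and 4 in stage III. Fewer controls per hormone by themselves lower calls and correlations. The drop in the splits therefore does not measure what the shared controls added. Over the 4 hormone comparisons 363 spots were called, 27 rose in all 4, 10 fell in all 4 and none had opposite calls.

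FSH and LH arrays were also compared directly. In stage I-II, clone tcad0009.j.11 was 1.98-fold higher with FSH (8.01 ± 0.23 against 7.02 ± 0.09, SD, n = 6; limma adjusted p = 9.4e-09), and in stage III 1.75-fold higher (7.62 ± 0.17 against 6.82 ± 0.13, SD, n = 6; limma adjusted p = 2.9e-06), where 5 of the 6 LH arrays were above background. Clone 1rt83h14_d_d07 was 1.75-fold higher with FSH in stage I-II (limma adjusted p = 1.2e-05) and touched a spot over 4 times brighter. Clone tcba0015.e.19 was 1.76-fold higher with FSH in stage III (limma adjusted p = 0.0028). In stage I-II 7 spots were higher and 1 lower with FSH, and in stage III 28 were higher and 10 lower. With equal block medians the counts were 14 in stage I-II and, in stage III, 124 (86 higher and 38 lower). The deposited log2 table gave 2 higher and 3 lower in stage I-II, and 11 higher and 4 lower in stage III. Lower with FSH were tcbk0003.k.11 in stage I-II, by -0.51 on the log2 scale (limma adjusted p = 0.043), and in stage III position N02-E07, which has no clone assigned, by -0.73 (limma adjusted p = 0.0070) and tcag0001.d.09 by -0.63 (limma adjusted p = 0.026). The IDs tcbk0003.k.11 and tcag0001.d.09 rest on less distinct matches than the other named IDs. All 3 spots touched one over 4 times brighter. For tcag0001.d.09 the brighter spot was tcag0001.c.01, named above for its fall with FSH in stage III. In that stage tcag0001.c.01 averaged 12.69 with FSH and 13.21 with LH, so these 2 clones may not be separate results. The calls of all 3 spots ended in a fit on the compared groups alone. There 4 and 12 spots were called at the 2 stages, none of them lower. The calls of tcbk0003.k.11 and tcag0001.d.09 were also lost in the deposited log2 table (limma adjusted p = 0.163 and 0.190) and in 9 of 12 and 5 of 12 fits with 1 array left out, and that of tcag0001.d.09 with array weights (limma adjusted p = 0.077). Leaving out stage I-II FSH replicate 28 or 29 left 5 calls in each case, and leaving out stage III LH replicate 68, 71 or 72 left 24, 25 and 21.

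Culture without hormone changed far more spots. In stage I-II, clone tcbk0062.j.01 was 29.6-fold higher after culture (12.70 ± 0.24, n = 6, against 7.81 ± 0.17 at T0, n = 3; SD; limma adjusted p = 8.6e-24), and tcbk0019.f.14, not well above background at T0, was at least 21.1-fold higher (limma adjusted p = 1.3e-28). Clones tcba0024.p.18 and tcbk0040.p.09 were 8.64-fold (limma adjusted p = 2.4e-18) and 8.52-fold lower (limma adjusted p = 3.3e-20), and tcba0024.p.18 touched a spot over 4 times brighter. In stage III, clones 1rt39g22_c_d11 and 1rt146k24_c_f12 were 23.5-fold (limma adjusted p = 5.0e-24) and 20.2-fold higher (limma adjusted p = 2.0e-28), and tcba0024.p.18 and tcba0009.n.04 were 4.67-fold (limma adjusted p = 1.4e-13) and 4.42-fold lower (limma adjusted p = 3.2e-14). In stage I-II 1469 spots rose and 1645 fell, and in stage III 1511 and 1739. Of these, 958 rose and 749 fell at both stages, and 62 had opposite calls. Without spots touching one over 4 times brighter, 1672 and 1893 spots were called, and with the control spots' level as covariate 2184 and 1732. With touching calls counted once, 544 rose and 479 fell in stage I-II and 557 and 581 in stage III.

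The stages were compared before and after culture. At T0, clone tcbk0044.i.21 was 9.90-fold higher in stage III (9.73 ± 0.19 against 6.42 ± 0.17, SD, n = 3; limma adjusted p = 4.0e-13). Clone tcab0001.j.04, not well above background in stage I-II, was at least 8.55-fold higher (limma adjusted p = 1.8e-17) and touched a spot over 4 times brighter. Clones 1rt113p07_b_h04 and tcbk0059.j.01 were 8.05-fold (limma adjusted p = 2.0e-14) and 5.26-fold lower (limma adjusted p = 4.0e-13). In all, 1243 spots were higher and 1180 lower in stage III. Among cultured controls, clones tcba0019.j.11 and tcay0035.a.07 were 4.32-fold (limma adjusted p = 3.6e-10) and 3.66-fold higher in stage III (limma adjusted p = 1.6e-15), the first above background on 4 of the 6 stage I-II arrays, tcad0008.j.15 and tcay0009.l.07 were 4.48-fold (limma adjusted p = 5.7e-16) and 3.42-fold lower (limma adjusted p = 1.5e-14), and 599 spots were higher and 669 lower. At both times 413 were higher and 303 lower, and 26 had opposite calls. The labels do not tie samples to fish, so stage cannot be told apart from the fish used. Without spots touching one over 4 times brighter, 1381 spots were called at T0, and with the control spots' level as covariate 645 were called among cultured controls. With touching calls counted once, 1015 were called at T0 and 776 among cultured controls. The filter above the median gave 1522 at T0.

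Whether the response itself differed by stage was tested as an interaction. For FSH, 1 spot passed, clone 1rt65f10_d_c05. This bright spot had group means from 12.94 in stage I-II Ctrl to 14.75 in stage I-II T0. Whether the scanner's ceiling limited its readings was not examined. Its log2 change was 1.22 in stage I-II (limma adjusted p = 2.3e-09) and 0.24 in stage III (limma adjusted p = 0.60). The difference was -0.98 ± 0.18 SE (limma adjusted p = 0.028). With median centring, the deposited log2 table and the compared groups alone the difference was -0.68, -0.90 and -0.98, and its call was lost (limma adjusted p = 0.081, 0.475 and 0.089). It was also lost in 11 of 24 fits with 1 array left out, and over all 24 the difference ran from -1.06 to -0.86. The count ran from 0 to 4 when single arrays were left out and reached 9 with equal block medians. For LH no spot passed in limma, 548 had an unadjusted p under 0.05, and 1 passed with equal block medians. For FSH 472 spots had an unadjusted p under 0.05, and about 451 of 9024 are expected by chance for either hormone.

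Control positions were read on the same arrays. The median signal of the 128 positions taken as the repeated control was 730 ± 206 at T0 and 285 ± 69.9 in Ctrl of stage I-II (SD, n = 3 and 6 arrays), and 577 ± 484 at T0 and 120 ± 25.2 in Ctrl of stage III. With FSH and LH it was 199 ± 25.3 and 124 ± 18.4 in stage I-II (SD, n = 6 each), and 127 ± 21.9 and 131 ± 31.5 in stage III. Median clone signals were 114 ± 9.27 over the 6 T0 arrays and 132 ± 24.8 over the 36 cultured arrays.

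**Figure D4:**
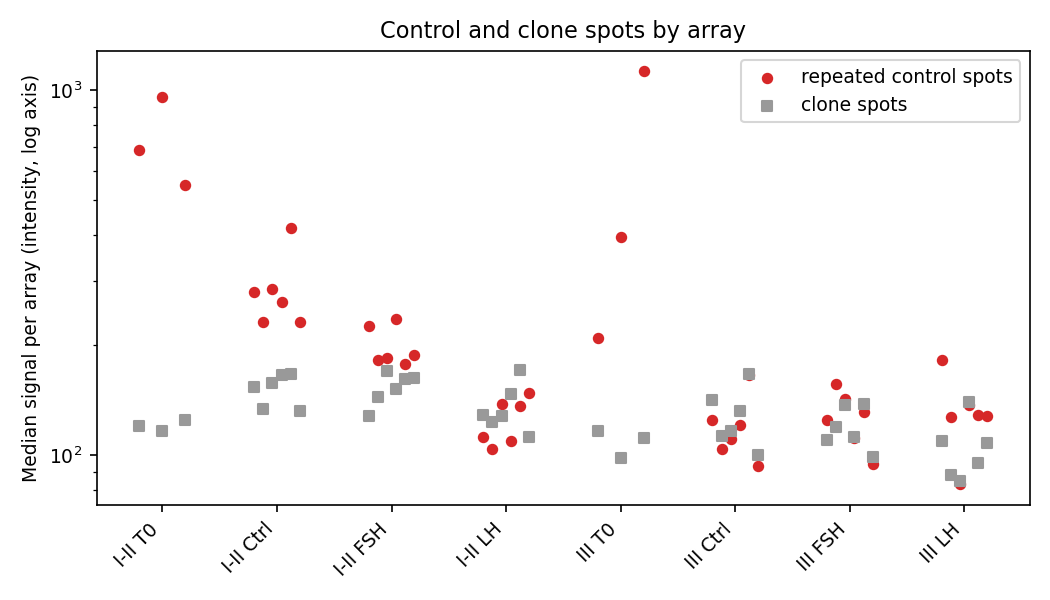
Median intensity per array on a log axis (y) of the repeated control positions (red circles) and of clone positions (grey squares) in the 8 groups (x); each array has 1 of each. Control medians reach 1126 at T0 and lie between 83 and 420 after culture.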

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

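Side-by-side pairs, array brightness and the dim control row were tested only after the results they concern were seen. The other tests were set down first, although the patterns had been seen.

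Spots called with FSH in stage I-II lay beside spots called in the same direction more often than chance placed them, with 32 side-by-side pairs against a mean of 2.93 in random placements. By the order of their IDs, clones lying side by side come from different source plates, and that excess of 10.9 times argues against relatedness within a plate. Spots 3 or 4 positions away shifted 0.30 times as much as touching ones (95% bootstrap interval 0.24 to 0.38), which argues against regional brightness as the whole cause. Signal spilling from a brighter spot may account for part: touching spots over 4 times dimmer shifted 0.073 more (log2) than those at least as bright (0.032 to 0.116), and the difference was 0.040, 0.081 and, with an interval that includes 0, 0.016 for FSH in stage III, LH in stage III and LH in stage I-II. Touching spots at least as bright also shifted, by 0.11, which spill was not shown to explain. Biology was not tested, because the files used do not pair clones with genes.

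Signal in control spots, outside the main measurement, was 2.56 times as high at T0 as in cultured controls in stage I-II and 4.81 times in stage III. Without stage III T0 replicate 5, which read 1126 against 210 and 396 on the others, the latter was 2.52 times. Overall brightness does not account for it, since the ratio to clone signal was 4.64 times as high at T0 as on cultured arrays. Signal added to every spot would raise the dim control row, whose mean differed by -4.67 units between T0 and cultured arrays. With the control level as covariate 2184 spots were called for culture in stage I-II. Of these, 2090 were among the 3114 called without it. The slope of the covariate comes from differences within groups. Those calls thus withstood a linear adjustment with that slope, which cannot exclude a relation acting between T0 and cultured arrays. In stage III 1664 of 3250 were shared, in cultured controls between stages 608 of 1268, for FSH in stage I-II 180 of 233 and for LH in stage I-II 46 of 158. Since the level follows the groups, whether it carries the calls, kept or lost, stays open. What the control ID measures is not given in the sources used here, and no biological explanation was tested.

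Clones that responded to FSH in stage I-II tended to be lower in stage III on the T0 arrays, which that comparison does not use. Of the 148 that rose, 75 were called lower and 7 higher, and of the 85 that fell, 53 and 1. Over all 9024 spots, 1180 were called lower and 1243 higher. The median stage difference was -0.47 (log2) for the 148 that rose and -0.55 for the 85 that fell, outside the central 95% of 10000 lists matched on signal (-0.08 to 0.06 and -0.11 to 0.09), which argues against signal level. Without spots touching far brighter ones the medians were -0.50 and -0.55, which argues against spill from far brighter neighbours. Carry-over between spots of similar brightness was not tested. The pattern was not particular to this comparison. For FSH in stage III the medians were -0.31 for the clones that rose and -0.91 for those that fell. For LH they were -0.36 and -0.47 in stage I-II and -0.42 and -0.49 in stage III. Each lay below the central 95% of its matched lists. The random lists ignore that neighbouring spots move together, so their intervals are too narrow. A difference between the stages and one between the fish used both stay open, and neither was tested.

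A test of 114 sets of 6 values for a sample standing apart, in which chance gives about 1 in 20, singled out 9. The T0 groups, with 3 arrays each, were too small for this test. For clone tcay0031.p.13, stage I-II FSH replicate 27 read 9.01 against 10.48 to 10.71 on the others. The repeated control read 420 on stage I-II Ctrl replicate 19. Position N02-E07 read 8.78 on stage I-II Ctrl replicate 19. Clone 1rt34l03_b_f02 read 8.68 and tcad0001.l.19 read 6.62 on stage III LH replicate 68. Clone tcbk0039.n.08 read 8.42 on stage III LH replicate 67. Clones above background were 58.7% on stage III Ctrl replicate 57. Clone 1rt83h14_d_d07 read 5.72 on stage III Ctrl replicate 55, and P01-F04 read 8.69 on stage III Ctrl replicate 60. The FSH response of 1rt65f10_d_c05 differed between stages by -0.98 (log2) in the interaction test.

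Other splits of the arrays were counted for each comparison. The real groups alone reached their count, 1 of 100 splits, for FSH (233 spots, highest other split 45) and LH (158, 49) in stage I-II. The same held for FSH (166, 33) and LH (74, 16) in stage III, FSH against LH in stage III (38, 3) and stage in cultured controls (1268, 584). For culture in stage I-II (3114, 640) and III (3250, 1001) it was 1 of 84. A chance division of these samples is thus an unlikely source of these counts, although such shares are the smallest the splits can give. The splits shuffle single samples, so they cannot exclude another difference that follows the groups. The fish used may be one, for stage in cultured controls as for the other comparisons, since the labels do not tie samples to fish. The control spots' level also differed between some groups. For FSH against LH in stage I-II, 4 of 100 splits, the real one included, gave 8 or more. One of them gave 33, several times the real count, which points to a structure of these samples that was not tested. For the FSH interaction chance cannot be excluded, as 6 of 100 splits gave at least 1 spot (highest 198). For the LH interaction the real count is 0, which all 100 splits reach by construction (highest 13), so the splits say nothing there. The 10 splits at T0 are too few for a share under 0.05 (2423 real, highest other 4).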

How the results depend on the processing

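The deposited log2 table, in place of scanner values, gave 140 calls for FSH and 243 for LH in stage I-II, 46 for LH in stage III, 5 and 15 for FSH against LH in stages I-II and III, 0 for the FSH interaction and 31 clones shared by FSH and LH in stage III. Fits on the compared groups alone gave 38 for LH in stage III, 4 and 12 for FSH against LH and 0 for the FSH interaction. Array weights gave 373 for LH in stage I-II. The FSH interaction gave 5 with median centring, 8 with cyclic loess, 4 and 3 with the filters above the lower quartile and the median, and 6 with array weights. The filter above the median, which tests fewer spots, gave 2067 and 2124 for culture and 1522 for stage at T0. An adjusted p under 0.01 gave overlaps of 62 and 31 between hormones and 26 between stages for LH.

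These alternatives were added after seeing the data. Equal block medians gave 350, 298, 357 and 120 for FSH I-II, FSH III, LH I-II and LH III, 14 and 124 for FSH against LH, and 9 and 1 for the interactions. The fitted signal gave 135 and 76 for FSH and LH in stage I-II, 18 for FSH against LH in stage III and 0 for the FSH interaction. The control level as covariate gave 50 for LH and 5 for FSH against LH in stage I-II, 1732 for culture in stage III, 645 for stage in cultured controls and 2 for the FSH interaction. Control spots kept in normalization gave 4 for that interaction. Leaving out spots beside far brighter ones, which tests fewer spots, gave 140 for FSH and 5 for FSH against LH in stage I-II, 1672 and 1893 for culture and 1381 for stage at T0. Counting touching calls once gave 1023 and 1138 for culture, 1015 for stage at T0 and 776 in cultured controls; with so many calls some touch by chance. Without the 3 arrays of another export order FSH against LH in stage III gave 25 and the FSH interaction 0. The background threshold on log2 values put 53.6% of clones above it, against 70.6%. Except for fewer spots tested, the cause was not tested.

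Leaving out each array gave 5 to 10 and 21 to 44 calls for FSH against LH in stages I-II and III and 0 to 4 for the FSH interaction, the other counts staying within 1.5 times. Named clones were run with median centring, the deposited table, trended and robust moderation, array weights, the compared groups alone and single arrays left out, and none reversed there. Of their values 186 kept and 13 lost the call under the settings other than leaving out an array, and 412 kept and 32 lost it with an array left out. Folds are lower bounds only for clones above background on no array of a group. Normexp variants, 1 value per gene and the gene list tests could not be run, for want of a background column and of gene names.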
